A study of Mus musculus with 11 samples.

How the data were processed

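RNA sequencing was carried out on primary neurospheres, which are floating cultures of neural stem and progenitor cells, from mouse embryos at E15.5. Per the labels, 6 libraries came from control embryos and 5 from embryos with Klf5 overexpression; how Klf5 was overexpressed is not given in the sources used here. Each library was treated as a separate embryo, since the labels' protocol counts 6 control and 5 overexpression embryos. Per the labels' protocols, total RNA was extracted and 2 library kits were used, of which at least one keeps strand; which library was made with which kit, and whether ribosomal RNA was removed, is not given in the sources used here.

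The deposited values are TPM, a unit in which all transcripts of a library add up to 1000000, although the rows given add up to 730832 to 846780 per library, in 1 table with 1 column per library, which the authors made before deposit. The submitters' processing notes list HISAT2, StringTie, HTSeq and DESeq2 and the mouse build GRCm38.p5, without versions, order or the part each tool played. The annotation release and the strand setting of the quantification are not given in the sources used here, so reads of overlapping genes may be mixed. Of the genes named by the rule below, these overlap other tested genes: Nkx6-2 (Inpp5a), Nrn1 (Fars2), Kcnk2 (Pdcd5-ps and A430027H14Rik), Htra1 (Fgfr2), Klf3 (Gm20033 and C230096K16Rik), Slc1a3 (Gm37310), Sstr2 (Slc39a11), S100b (Dip2a), Fgfr3 (G630022F23Rik), Egfl7 (Agpat2 and Gm20532), Ccna2 (Exosc9), Irf9 (Rnf31), Pfkp (Pitrm1), mt-Nd2 (mt-Tw) and mt-Co3 (mt-Atp6). TPM divides by transcript length and by the library's total, so a large change in a few abundant transcripts moves the values of all others. The table held 53453 gene rows, of which 53255 could be matched to a symbol and 25352 were 0 in every library. Gene identifiers are those of the table, and symbols were matched to them from a separate reference list of gene names. Coordinates, with starts counted from 1, come from the GENCODE M21 annotation of GRCm38.

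TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given. Precision was taken from the spread between libraries. With 5 and 6 libraries an exact permutation test runs over all splits of the libraries. The smallest two-sided p is 0.00216 for Klf5, Klf4 and gene lists, where differences as large in either direction were counted. For library measures and summed TPM of lists the smaller tail was doubled, so the smallest p is 0.00433.

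Before the data were examined, the following were fixed: the main test, the thresholds, 28 gene lists with 441 different genes, the rule for naming genes and most alternatives. Genes with at least 1 TPM in at least 5 libraries were kept, which left 13549. Values were taken as log2(TPM + 1), with a pseudocount of 1, and tested with limma 3.58.1 (R 4.3.3), with a mean-dependent variance trend, a two-sided test and Benjamini-Hochberg adjustment at 0.05. No covariate was used in the main test. A fold change on this scale understates the change of genes near 1 TPM, so the ratio of mean TPM is given beside it for leading genes. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. The same lists were also tested with fry, which compares a list with no change rather than with other genes. Camera could be run on 21 lists; 7 lists had too few tested members. The older symbols Cyr61 and Ctgf were matched to Ccn1 and Ccn2. Where several rows shared a symbol, the protein-coding row with the lowest identifier kept it. Single values per library were compared by two-sided exact permutation tests with Python 3.11.15 and scipy 1.17.1.

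Named genes are Klf5 and Klf4, then the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold. These needed a regular symbol, a mean of at least 1 TPM in the higher group and all 5 overexpression libraries on one side of the control mean. Each list added its 2 members with the smallest p, and up to 2 more where 3 or more members passed. The rule gave 77 genes, of which 51 passed the threshold. The values of 1 of the genes are not reported here. Other changed members of a list are named as chosen after their values were seen.

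The alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, trimmed-mean scaling with 30% of ratios and 5% of levels trimmed from each end, quantile normalization, removal of mitochondrial and haemoglobin genes, array weights, no variance trend, robust variances, a sex covariate, the replicate number as a block, a fold change limit, an adjusted p under 0.1, and leaving out each of the 11 libraries. The block was fitted on 10 libraries, which were also fitted without it. That fit without the block is identical to leaving out control library 6. It is counted both among the 13 other fits and among the 11 with a library left out. Chosen after seeing the data were lists without shared members and the removal of 5 ribosomal RNA-like rows together with mt-Rnr1 and mt-Rnr2, the mitochondrial ribosomal RNA genes. The remaining values were rescaled to 1000000 per library. Fits described as without the ribosomal RNA-like rows lack all of these rows, whereas the share of each library given for such rows covers the 5 alone. The sex covariate used the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty against Xist. The limma procedure was tested on simulated data with 13550 genes in the same design. It recovered 70% of 50 genes raised by 1 and 70% of 50 genes lowered by 1 on the log2 scale, and 96% and 98% of those moved by 2 and -2. Of 179 calls 12 were false, and 1 gene was called when nothing had been changed. Changes were given only to genes with a mean of at least 2 TPM, and noise was drawn for each gene without correlation between genes. These rates therefore check the procedure and may not hold for genes near the floor or for correlated genes.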

Results

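Transcript levels were measured by RNA sequencing in primary neurospheres from embryonic mouse brain, in 5 libraries with Klf5 overexpression and 6 control libraries. All values are TPM as deposited, and sequencing depth is unknown. The listed values of a library summed to 784942 ± 35448 TPM (SD, n = 5) with overexpression and 830176 ± 12100 TPM (SD, n = 6) in controls, with an exact permutation p of 0.013, or 0.0909 after adjustment over 7 library measures. If TPM was scaled over all transcripts, 17.8 to 26.9% of each overexpression library and 15.3 to 18.6% of each control library lay outside the rows given; which transcripts these are is unknown, and every TPM comparison here carries this difference. Rows that resemble ribosomal RNA, led by Gm42418, took 20.3% ± 7.35 (SD, n = 5) and 22.3% ± 4.71 (SD, n = 6) of these totals, with an exact permutation p of 0.576. Genes above 0 numbered 18374 to 20882 per overexpression library and 18021 to 19122 per control library. Across genes, which are not independent replicates, the Pearson correlation of log2 values between any pair of libraries lay between 0.938 and 0.968.

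The design asks which genes of neural precursors differ when Klf5, a zinc finger transcription factor of the Kruppel-like family, is overexpressed. Klf5 (ENSMUSG00000005148, chromosome 14, 99298691 to 99315036, plus strand, GRCm38) stood at 75.8 ± 18.5 TPM (SD, n = 5) in the overexpression libraries and 0.849 ± 0.297 TPM (SD, n = 6) in controls, an 89.2-fold ratio of means. The lowest overexpression library had 53.6 TPM and the highest control 1.29 TPM. The log2 fold change was 5.36 ± 0.19 (SE), with a limma adjusted p of 9.08e-11 and a two-sided exact permutation p of 0.00216, the smallest that the splits of 11 libraries allow. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466, minus strand), the family member that the study's title sets beside Klf5, had 7.18 ± 2.50 TPM (SD, n = 5) against 4.37 ± 1.87 TPM (SD, n = 6). Its log2 fold change of 0.63 ± 0.27 (SE) did not pass the test (limma adjusted p = 0.322, exact permutation p = 0.0649), and 4 of 5 overexpression libraries lay above the control mean.

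**Figure D1:**
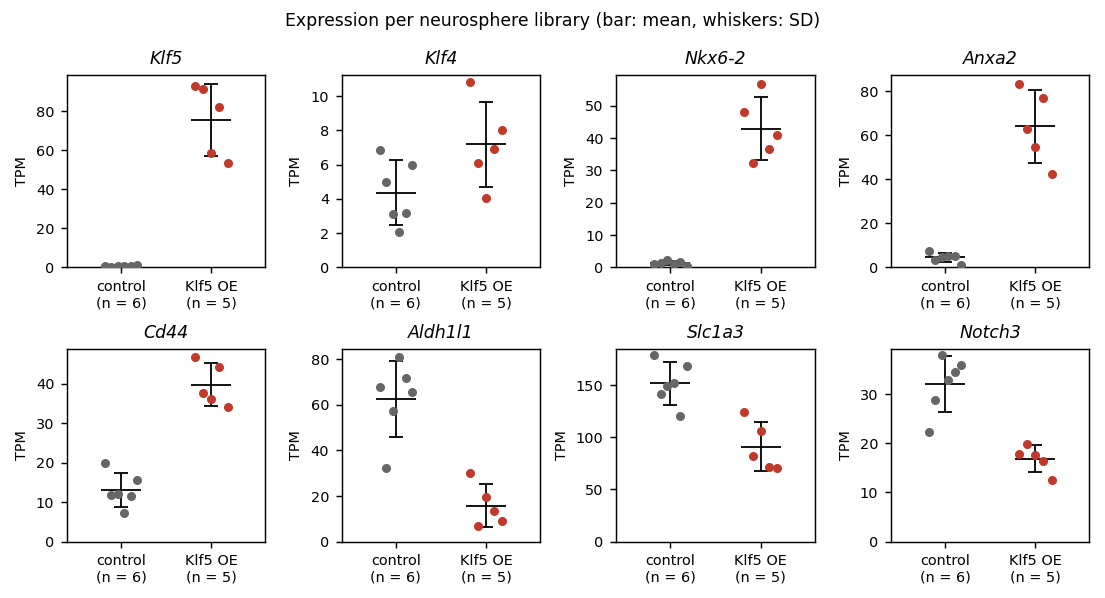
TPM of 8 genes in each library, on linear axes that start at 0, for 6 control and 5 Klf5 overexpression (OE) libraries; points are libraries, horizontal bars are means and whiskers are SD. Klf5 lay between 53.6 and 93.0 TPM with overexpression and at or below 1.29 TPM in controls, whereas the Klf4 values of the groups overlapped.

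Among the genes that rose with Klf5 overexpression, the largest change on the log2(TPM + 1) scale after Klf5 itself was in Nkx6-2, a homeobox transcription factor of ventral neural progenitors and oligodendrocytes, at 42.9 ± 9.75 TPM (SD, n = 5) against 1.32 ± 0.586 TPM (SD, n = 6). Nrn1 (neuritin, a neurite growth factor) rose from 2.52 to 49.7 TPM, a 19.7-fold ratio that was 30.6 without control library 1, and Anxa2, a calcium-dependent phospholipid-binding protein, from 4.53 to 64.0 TPM. Among the genes that fell, Tnnt1, the slow skeletal muscle troponin T, went from 29.6 ± 6.29 TPM (SD, n = 6) in controls to 2.94 ± 2.22 TPM (SD, n = 5). Cbs, an enzyme that makes cystathionine from homocysteine, fell from 24.8 to 4.40 TPM, and the brain metallothionein Mt3 from 309 to 80.3 TPM. In all, 504 of 13549 tested genes changed at a limma Benjamini-Hochberg adjusted p under 0.05, of which 310 were higher and 194 lower.

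The log2 fold changes of Nkx6-2, Nrn1, Anxa2, Tnnt1 and Cbs were 4.25 ± 0.21, 3.87 ± 0.39, 3.63 ± 0.29, -3.10 ± 0.28 and -2.40 ± 0.26 (SE). Their limma adjusted p were 6.12e-09, 2.12e-05, 1.16e-06, 5.33e-06 and 3.80e-05. Nkx6-2 lies on chromosome 7 (139579376 to 139582797) and overlaps Inpp5a, and Nrn1 overlaps Fars2, so reads of these pairs could be mixed if strand was not used. Of the 504 changed genes, 197 rose and 75 fell by at least 1 on the log2 scale. The number of lower genes was 95 without a filter on low values, 301 with trimmed-mean scaling, 311 with quantile normalization, 300 without the ribosomal RNA-like rows, 123 without overexpression library 2 and 126 without control library 3.

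**Figure D2:**
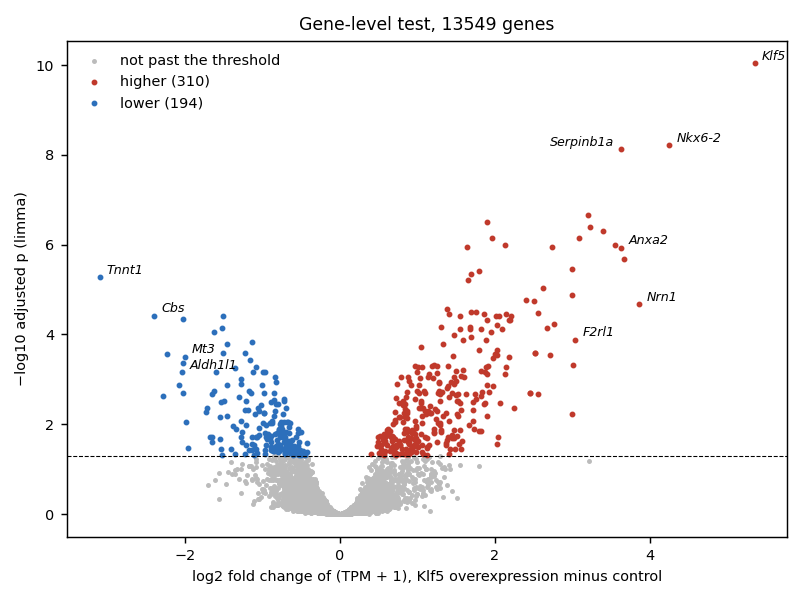
Each point is 1 of 13549 tested genes, with its log2 fold change of (TPM + 1), overexpression minus control, on the x axis and −log10 of its limma adjusted p on the y axis; the dashed line is an adjusted p of 0.05. The 310 higher genes (red) reach larger fold changes than the 194 lower genes (blue), with Klf5 at 5.36 and Tnnt1 at -3.10.

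Several other strongly raised genes were near the detection floor in controls. Serpinb1a, an inhibitor of neutrophil serine proteases, had 12.4 ± 1.77 TPM (SD, n = 5) and at most 0.117 TPM in any control library. Lbhd2 was listed at 0 in each of the 6 control libraries and at 5.65 to 14.0 TPM in the overexpression libraries, so no fold is given. The channel gene Kcnn4, a calcium-activated potassium channel, rose 21.2-fold in mean TPM (34.5-fold without control library 6), the kallikrein Klk10 32.5-fold, the tyrosine phosphatase Ptpn6 17.8-fold and the heat-shock family member Hspa12b 19.8-fold. The RNA-binding protein gene Rbpms rose from 0.168 to 9.02 TPM, a ratio of 53.7 that was 144 without control library 3, and F2rl1, a protease-activated receptor, from 0.135 to 10.6 TPM with an SD of 9.15 TPM across the 5 overexpression libraries; its ratio of 78.2 was 142 without control library 1 and 49.9 without overexpression library 1. Limma log2 fold changes of these 8 genes lay between 3.04 (F2rl1) and 3.67 (Kcnn4).

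The other strongly lowered genes included several enzymes. Kyat3, a kynurenine aminotransferase, fell 15.48-fold in mean TPM, the ferric reductase Cybrd1 7.92-fold and Pla2g7, which inactivates platelet-activating factor, 7.26-fold (37.3-fold without overexpression library 2). Aldh1l1, a folate enzyme used as an astrocyte marker, fell from 62.6 ± 16.7 TPM (SD, n = 6) to 15.8 ± 9.27 TPM (SD, n = 5), with a log2 fold change of -2.04 ± 0.30 (SE) and a limma adjusted p of 0.000692. The serine proteases Prss23 and Htra1 fell 8.91-fold (26.7-fold without overexpression library 1) and 3.43-fold, the guanylate-binding protein Gbp3 5.61-fold, the potassium channel Kcnk2 4.81-fold (10.4-fold without overexpression library 4) and A2m, a broad protease inhibitor, 4.01-fold. The Htra1 call was lost without a filter on low values (adjusted p = 0.0833). Kyat3, Cybrd1, Pla2g7 and Prss23 had means of 9.89 TPM or less in both groups. The Htra1 gene overlaps Fgfr2.

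Radial glia and neural stem cell markers moved in both directions. Of 20 tested members, 5 fell and 2 rose, and 12 (10 lower) passed when adjusted over the list alone. Ednrb, an endothelin receptor, fell from 93.1 ± 10.5 TPM (SD, n = 6) to 44.1 ± 11.2 TPM (SD, n = 5), Sox3, a transcription factor of neural progenitors, from 198 to 123 TPM, and the glutamate transporter Slc1a3 from 152 to 90.8 TPM. Limma adjusted p were 0.00054, 0.00429 and 0.00892 for Ednrb, Sox3 and Slc1a3. Tnc and Msi1 also fell, with log2 fold changes of -0.85 and -0.64, while Vim (vimentin) rose by 0.53; these 3 were chosen after their values were seen. Hes1, a Notch target, rose from 37.3 to 57.2 TPM (limma adjusted p = 0.017, and 0.00663 to 0.052 with each library left out), and lost its call without overexpression library 2. Camera placed the list lower than other genes (adjusted p = 0.00145), but not with an estimated correlation (adjusted p = 0.918).

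Notch pathway genes also moved both ways, with 3 higher and 3 lower among 14 tested members and 8 (5 lower) past the threshold when adjusted over the list alone. The receptor Notch3 fell from 32.0 ± 5.72 TPM (SD, n = 6) to 16.8 ± 2.76 TPM (SD, n = 5), a log2 fold change of -0.89 ± 0.16 (SE), and the ligand gene Dll3 rose from 70.6 to 127 TPM, a log2 fold change of 0.86 ± 0.15 (SE). Lfng, a glycosyltransferase that modifies Notch, fell from 87.7 to 54.8 TPM; its limma adjusted p was 0.0188, with 0.0023 to 0.0516 when each library was left out and the highest value without overexpression library 2, and the call was also lost without a filter on low values (0.0804) and with the replicate block (0.0514). The ligand gene Jag1 rose by 0.83 and the Notch target Hey1 fell by 0.78 on the log2 scale, both chosen after their values were seen. Hes1 was the third higher member. Camera gave an adjusted p of 0.689 for the list.

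Of 15 tested astrocyte markers, 4 rose and 2 fell, and 10 (5 of them lower) passed when adjusted over the list alone. Cd44, a hyaluronan receptor, rose from 13.02 ± 4.30 TPM (SD, n = 6) to 39.8 ± 5.50 TPM (SD, n = 5), the receptor Fgfr3 from 39.7 to 107 TPM and S100b from 0.956 to 8.42 TPM. Sparcl1, chosen after its values were seen, rose from 21.01 to 79.1 TPM. The lower members were Aldh1l1 and Id3, of which the Id3 call was lost in 9 of 11 fits with 1 library left out and in 10 of 13 other fits. Camera gave an adjusted p of 0.213 for the list. S100b overlaps Dip2a.

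**Figure D3:**
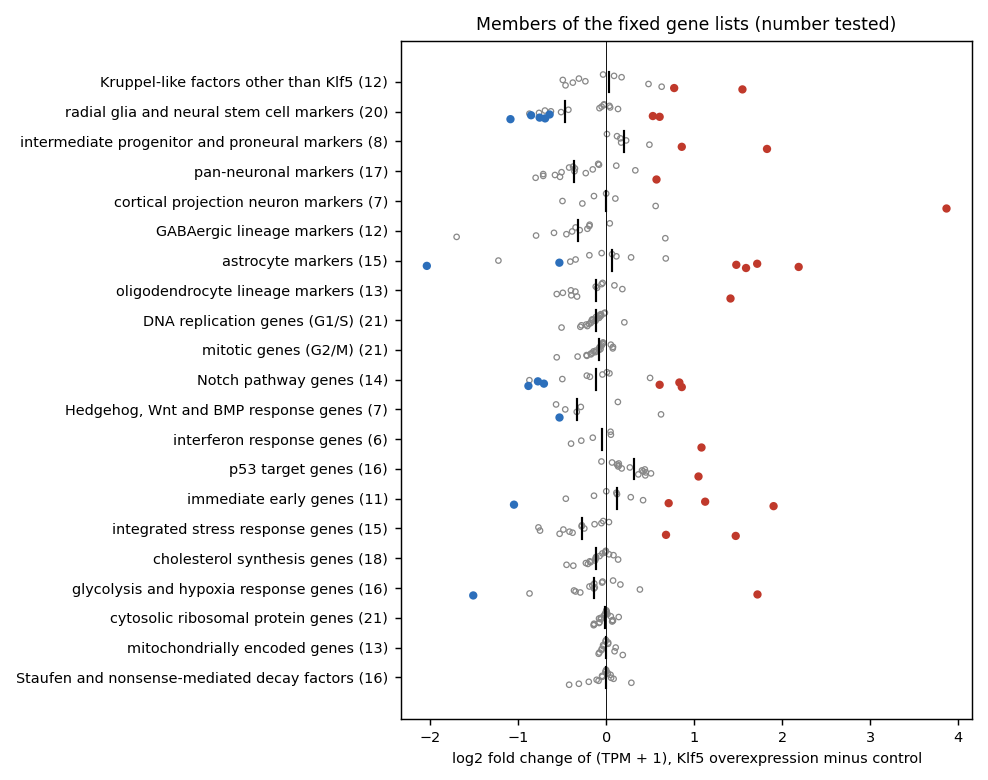
Log2 fold changes of (TPM + 1), overexpression minus control, of the tested members of 21 fixed gene lists, with the number tested in brackets; filled points passed the limma adjusted p of 0.05 (red higher, blue lower), open points did not, and black ticks are list medians. Radial glia, astrocyte and Notch members passed in both directions, and no member of the GABAergic, replication, mitotic, cholesterol, ribosomal protein, mitochondrial or decay factor lists passed.

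Intermediate progenitor and proneural markers had 2 higher members among 8 tested, and 2 when adjusted over the list alone. These were Dll3 and Sstr2, a somatostatin receptor that stood at 3.33 ± 1.30 TPM (SD, n = 5) against 0.194 ± 0.271 TPM (SD, n = 6) and overlaps Slc39a11; the ratio of 17.2 was 34.4 without control library 4. All 8 members had log2 fold changes above 0, but 93 of all splits of the libraries put all 8 on one side of 0 (exact permutation p of 0.268 for the median and 0.00866 for the mean of 0.48, neither adjusted over lists). Camera placed the list higher (adjusted p = 0.000792), but not with an estimated correlation (adjusted p = 0.918). Neuronal lists showed few changed members. Of 17 pan-neuronal markers 14 lay below 0, with a median of -0.36, as at least 14 on one side did in 209 of all splits of the libraries (exact permutation p of the median 0.186). Only Mapt, the tau gene, passed, and it was higher, at 32.0 ± 3.95 TPM (SD, n = 5) against 21.5 ± 4.84 TPM (SD, n = 6); its limma adjusted p of 0.0474 rose above the threshold in 9 of 11 fits that each left out 1 library (range 0.00817 to 0.122), and in 3 of 13 other fits. Adjusted over the list alone, Mapt passed, and so did 3 lower members: Rbfox3, with 2.17 against 4.83 TPM (limma adjusted p over all genes 0.128), and Gap43 and Syt1, both chosen after their values were seen. Of 7 cortical projection neuron markers Nrn1 alone passed, with 2 past the threshold when adjusted over the list alone, and Sox5 had 22.1 against 14.99 TPM (limma adjusted p = 0.175). None of 12 GABAergic lineage markers passed in limma, with 1 when adjusted over the list alone; Sst had 1.90 against 9.85 TPM (adjusted p = 0.224), a ratio of 5.19 that was 11.8 without overexpression library 4. Camera gave adjusted p of 0.0885, 0.203 and 0.32 for the pan-neuronal, projection neuron and GABAergic lists, and called the pan-neuronal list lower in 5 of 24 other fits. The projection neuron median was just below 0 and changed sign with scaling, while the mean, led by Nrn1, was 0.52.

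Of 13 oligodendrocyte lineage markers 1 rose, and 1 passed when adjusted over the list alone. This was Cspg4, the NG2 proteoglycan gene of oligodendrocyte progenitors and pericytes, at 123 ± 22.7 TPM (SD, n = 5) against 45.7 ± 8.07 TPM (SD, n = 6), with a limma adjusted p of 3.58e-05. Olig1, a transcription factor of the same lineage, had 1075 against 1375 TPM and did not pass (limma adjusted p = 0.33), and camera gave an adjusted p of 0.713 for the list. Cspg4 was also the most abundant of the mural and mesenchymal markers, whose summed TPM was 128 against 53.5 (exact permutation p = 0.00433, the smallest possible for such sums, 0.0303 adjusted over 7 lists of other cell types). That rise was Cspg4 alone: the other 12 genes summed to 5.04 against 7.82 TPM (exact permutation p = 0.281). Of the 4 members of that list that could be tested, Cspg4 rose and Myl9, a myosin light chain gene, fell from 2.90 to 0.554 TPM, and both passed when adjusted over the list alone. The Myl9 call (limma adjusted p = 0.0454) was lost in 9 of 11 fits with 1 library left out, where it ranged from 0.0238 to 0.123, and in 8 of 13 other fits. Genes of other cell types were low: summed TPM was 2.10 against 1.94 for 15 microglia and macrophage genes, 2.61 against 2.26 for 11 endothelial genes, 0.122 against 0.271 for 10 erythroid genes and 0.905 against 1.201 for 16 epithelial genes. Choroid plexus and ependymal genes summed to 21.6 against 23.3 TPM, and naive pluripotency genes to 0.901 against 1.75 TPM (exact permutation p = 0.0303, 0.106 adjusted over the 7 lists). Of the few testable members Cd68, Egfl7, Nr5a2, Foxj1 and Dynlrb2, none passed in limma over all genes, and 1 of the 3 choroid plexus and ependymal members passed when adjusted over the list alone.

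Of 12 other Kruppel-like factors, 2 rose, and 2 passed when adjusted over the list alone. Klf10 rose from 37.0 ± 10.8 TPM (SD, n = 6) to 109 ± 21.96 TPM (SD, n = 5), with a limma adjusted p of 7.41e-05. Klf3 had 65.5 against 39.4 TPM and a limma adjusted p of 0.0451, which rose above the threshold in 8 of 11 fits with 1 library left out (range 0.0174 to 0.119) and in 4 of 13 other fits. Camera gave an adjusted p of 0.289 for the list, which contains Klf4.

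Of 11 immediate early genes, 3 rose and 1 fell, and 4 passed when adjusted over the list alone. Ier3 rose from 8.19 ± 2.72 TPM (SD, n = 6) to 32.4 ± 6.51 TPM (SD, n = 5) and the nuclear receptor gene Nr4a1 from 22.3 to 36.6 TPM, with limma adjusted p of 4.88e-05 and 0.00883. Ccn1, a matricellular protein gene, fell from 4.45 to 1.62 TPM. Egr3 had 2.89 against 0.862 TPM, a ratio of 3.36 that was 5.49 without control library 1, and its limma adjusted p of 0.0479 rose above the threshold in 10 of 11 fits with 1 library left out (range 0.0087 to 0.143), and the call was lost in 9 of 13 other fits. Camera gave an adjusted p of 0.0764 for the list, and 0.00319 without Ccn1, which had been matched through its older symbol; with an estimated correlation these were 0.918 and 0.555, and with fry 0.392 and 0.124.

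Among 16 p53 target genes only Cdkn1a, the p21 cell cycle inhibitor, passed, and 1 passed when adjusted over the list alone. Cdkn1a rose from 141 ± 51.1 TPM (SD, n = 6) to 281 ± 64.7 TPM (SD, n = 5), with a limma adjusted p of 0.0166 that ranged from 0.00833 to 0.0504 with each library left out and was highest without overexpression library 1; without a filter on low values it was 0.111 and the call was lost. Mdm2 had 46.3 against 34.3 TPM (limma adjusted p = 0.147), and 15 of the 16 members had log2 fold changes above 0, but 158 of all splits of the libraries put at least 15 on one side of 0 (exact permutation p of 0.102 for the median and 0.11 for the mean). Camera placed the list higher (adjusted p = 0.000183), but not with an estimated correlation (adjusted p = 0.918). Radial glia, proneural and p53 target genes were the 3 of 21 lists that camera called, and 80 of 100 splits of the 11 libraries gave at least 3 called lists.

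Cell cycle lists held no changed member in limma. Of 21 DNA replication genes 20 lay below 0, as at least 20 on one side did in 148 of all splits of the libraries. Of 21 mitotic genes 18 lay below 0, as at least 18 on one side did in 261 of all splits. Exact permutation p of the 2 medians were 0.383 and 0.554. Of the 21 DNA replication genes 1 passed when adjusted over the list alone, and of 21 mitotic genes 0. Ccne1 (cyclin E) had 13.9 against 20.1 TPM (limma adjusted p = 0.0578), Uhrf1 95.9 against 114 TPM, Ccnb2 16.5 against 23.8 TPM and Ccna2 101 against 124 TPM. Camera gave adjusted p of 0.102 for the replication list and 0.203 for the mitotic list, and called them lower in 4 and 2 of 24 other fits.

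Signalling, stress and metabolic lists had isolated changes. Of 15 integrated stress response genes 12 lay below 0 but 2 rose, and 2 passed when adjusted over the list alone: Nupr1, from 8.73 to 23.7 TPM (limma adjusted p = 0.0136, but 0.0971 without a filter on low values), and Ddit4, from 180 to 291 TPM (limma adjusted p = 0.024). At least 12 of the 15 lay on one side of 0 in 304 of all splits of the libraries. The Ddit4 call was lost without control library 1, control library 5, overexpression library 1 or overexpression library 3 (range 0.0086 to 0.0591), without a filter on low values, without the variance trend or with the replicate block (0.105, 0.0597 and 0.076). Of 16 glycolysis and hypoxia response genes the glucose transporter Slc2a1 fell from 25.1 ± 3.99 TPM (SD, n = 6) to 8.19 ± 1.64 TPM (SD, n = 5) and the phosphofructokinase Pfkp rose from 5.31 to 18.1 TPM (limma adjusted p = 0.00484, but 0.0508 without a filter on low values), and 3 (2 lower) passed when adjusted over the list alone. Among 6 interferon response genes Bst2 (tetherin) rose from 12.3 to 27.9 TPM, Irf9 had 2.24 against 3.34 TPM (limma adjusted p = 0.444), and 1 passed when adjusted over the list alone. Of 7 Hedgehog, Wnt and BMP response genes Id3, a target of BMP signalling, fell from 81.4 to 56.1 TPM, and 2 passed when adjusted over the list alone. The Id3 call (limma adjusted p = 0.0494) was lost in 9 of 11 fits with 1 library left out (range 0.0202 to 0.117) and in 10 of 13 other fits, and Id2 had 54.3 against 34.6 TPM (adjusted p = 0.0941). Camera gave adjusted p of 0.424, 0.248, 0.713 and 0.32 for the stress, glycolysis, interferon and signalling lists. The interferon median (-0.05) was below 0 while its mean (0.06) and camera direction were above it.

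No member passed in limma, over all genes or when adjusted over the list alone, among 18 cholesterol synthesis genes, 21 cytosolic ribosomal protein genes, 13 mitochondrially encoded genes and 16 Staufen and nonsense-mediated decay factors. Their members with the smallest p included Insig1 (166 against 215 TPM), Dhcr7 (73.2 against 90.4 TPM), Rps24 (936 against 1030.1 TPM), Rpl10a (615 against 670.5 TPM), mt-Nd2 (3134 against 2799 TPM), mt-Co3 (1399 against 1475 TPM), Stau2 (12.6 against 17.1 TPM) and Smg9 (18.3 against 22.4 TPM). Camera adjusted p were 0.343, 0.947, 0.808 and 0.808 for these lists. The medians of the ribosomal protein, mitochondrial and decay factor lists were each within 0.02 of 0 on the log2 scale and changed sign with scaling, and the mean and camera direction of the mitochondrial list were above 0 while its median was below.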

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

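Of 168 groups of libraries tested (77 named genes and 7 library measures, in each of both conditions), 10 held a library far from the others, against 8.4 that chance alone gives; no explanation was tested for them. Values are log2(TPM + 1). Control library 1 stood apart for Cybrd1 (4.48, others 2.85 to 3.32), Kyat3 (0.87, others 2.61 to 3.11) and A2m (2.45, others 3.63 to 4.32). Overexpression library 1 was high for Prss23 (1.61, others 0.08 to 0.42) and for A2m (2.99, others 1.51 to 1.85). Overexpression library 2 was high for Pla2g7 (2.40, others 0.05 to 0.39) and low for Mapt (4.70, others 5.09 to 5.16). Control library 3 was high for Rbpms (0.76, others 0.07 to 0.11), control library 5 low for Gbp3 (2.85, others 3.55 to 3.87) and control library 6 high for Mapt (5.01, others 4.28 to 4.41). The calls of Cybrd1, Kyat3, A2m, Prss23, Pla2g7, Rbpms and Gbp3 were kept with each of the 11 libraries left out.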

How the results depend on the processing

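The removal of ribosomal RNA-like rows was chosen after seeing the data. Changed genes numbered 349 to 735 under the 13 other fits and 386 to 496 with each library left out, against 504 in the main test. Of the 504 calls, 313 were kept in all 11 fits with a library left out. Counted separately, 272 of the 504 had a log2 fold change of at least 1 in size. Lower genes, 194 in the main test, numbered 95 without a filter, where 28101 genes were tested, 301 with trimmed-mean scaling, 311 with quantile normalization, 300 without ribosomal RNA-like rows, and 123 to 213 with each library left out, lowest without overexpression library 2 (123) and control library 3 (126); the cause was not tested. Called lists, 3 in the main test, numbered 7 without a filter, 5 with the 5 TPM filter, 0 with an estimated correlation and 3 to 6 with each library left out, where control libraries 1 and 2 and overexpression libraries 1 and 3 each raised it to 5 or 6. Fry, which tests a list against no change rather than against other genes, called 0. The direction of lists not called changed in 25 of 430 pairs of list and fit. Without Ccn1, which was matched through its older symbol, 4 lists were called. Of 51 called named genes, 35 kept their call in all 13 other fits, 42 in all 11 with a library left out and 34 in both, and 0 changed direction. Without a filter the calls of Htra1, Pfkp, Nupr1, Cdkn1a, Lfng and Ddit4 were among those lost, and F2rl1, Pla2g7, Prss23, Sstr2 and Ccn1 could not be tested with the 5 TPM filter. The uncalled Cd68 changed sign without control library 2 (0.044), control library 6 (0.10), overexpression library 3 (0.065) or overexpression library 5 (0.050), and ranged from -0.24 to 0.10 with each library left out; Egfl7, without a call either, ranged from -0.30 to 0.073, above 0 without control library 2 (0.0011) or overexpression library 1 (0.073). Replicate numbers did not pair the libraries: correlations of deviations for numbers 1 to 5 were 0.30, 0.06, -0.01, -0.04 and 0.02, and only for number 1 did the overexpression library correlate best with its own number. With the replicate block on 10 libraries 420 genes and 5 lists were called and Cd68 was at 0.10, against 408 genes and 3 lists in the same libraries without the block. The fit without the block is the same as the one without control library 6 and is counted in both sets of fits. Depth is unknown, so its limit on low genes cannot be given.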

Other observations

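The gene groups of the first 2 paragraphs here, the histone and small RNA groups, the Fisher and permutation tests of the fixed lists, and the tests on ribosomal RNA-like rows, other-lineage markers and fibroblast genes were chosen only after results had been seen; the sex covariate fit and the test of the DNA replication list were planned, but their use against an explanation was chosen after. A list of enzymes that break down branched-chain amino acids, and the products they share with other pathways, was drawn up after lower members had been noticed. All 28 tested members had log2 fold changes below 0, with a median of -0.46, and 8 fell (Oxct1, Abat, Dbt, Pcca, Ivd, Echs1, Hibadh and Mut). Oxct1, which activates ketone bodies, fell from 139 ± 11.1 TPM (SD, n = 6) to 63.6 ± 16.9 TPM (SD, n = 5), and Abat, the GABA transaminase, from 26.9 to 9.01 TPM. The median had an exact permutation p of 0.00216, the smallest possible, and 0.00866 after adjustment over 8 groups, while camera with an estimated correlation gave an adjusted p of 0.0637. The list and the 8 groups, which include a part of this list, were chosen after results had been seen. These p are therefore no independent evidence. Since 7 of the members prompted the choice of the list, the other 21 were tested alone: all 21 lay below 0, with a median of -0.27 and an exact permutation p of 0.026, or 0.0693 adjusted, while their mean of -0.33 had 0.00433, or 0.00866 adjusted, so a shift of the whole list is not settled. All 28 members lay on one side of 0 in 29 of all splits of the libraries into 5 and 6.

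Calcium-binding S100 genes, annexins, collagens and imprinted genes held some of the strongest single changes; these groups were chosen because members had been noticed, so their counts are no independent evidence. Of 8 S100 genes S100a10, a partner of Anxa2, rose from 101 ± 13.8 TPM (SD, n = 6) to 402 ± 94.9 TPM (SD, n = 5), S100a4 rose from 6.34 to 27.7 TPM, and S100b also rose. Of 6 annexins Anxa2 and Anxa6 rose, the latter from 86.7 to 287 TPM, and Anxa3 fell from 17.1 to 3.91 TPM. Of 14 collagen genes 4 rose (Col18a1, Col9a3, Col5a3 and Col16a1), with Col18a1 going from 1.79 to 21.8 TPM. Of 19 imprinted genes H19 rose from 3.28 to 18.97 TPM and Igf2 from 0.571 to 1.99 TPM (a ratio of 3.48, or 5.90 without control library 2), while Peg3 and Peg12 fell by 0.91 and 0.75 on the log2 scale.

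Changed genes of either direction were counted in the fixed lists against the 3.72% of all tested genes that changed. By one-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 23 lists, 5 lists held more than that share: radial glia (7 of 20, adjusted p = 6.88e-05), Notch (6 of 14, 6.88e-05), astrocyte (6 of 15, 7.41e-05), immediate early (4 of 11, 0.00291) and mural (2 of 4, 0.0363). These tests treat genes as independent, and several genes stand in more than 1 list. Of 24 other fits the radial glia, Notch and astrocyte lists passed in all 24, the immediate early list, which includes Egr3, in 20, and the mural list, which rests on Cspg4 and Myl9, in 4. Among the 24, the fit on 10 libraries without the block and the one without control library 6 are identical. Exact permutation of list medians gave 0 of 23 lists past adjustment, with the smallest p for radial glia (0.00649, adjusted 0.149), and that of list means also gave 0, with the smallest p for the proneural list (0.00866, adjusted 0.124). The smallest p that the splits allow is 0.00216, so a list standing alone could pass adjustment over 23 lists only at that value. These counts of 0 are therefore weak evidence that no list shifted.

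The first pattern weighed is the number of changed genes. Of 100 splits of the 11 libraries only the real one, 1 of 100, gave 504 changed genes, and the highest other gave 4; for higher genes it was 1 of 100 (310, highest other 1) and for lower genes 1 of 100 (194, highest other 3), so chance can be excluded for these counts. Ribosomal RNA load and embryo sex are argued against as the whole cause by their balance between the groups. Ribosomal RNA-like rows took 20.3% ± 7.35 (SD, n = 5) with overexpression and 22.3% ± 4.71 (SD, n = 6) in controls (exact permutation p = 0.576). Sex, read from Xist and Y-linked genes, gave 2 XY and 3 XX embryos with overexpression and 3 XY and 3 XX controls. Without the ribosomal RNA-like rows 97.2% of the calls remained, and 95.2% with a sex covariate. Given this balance most calls were likely to remain, so these percentages add little. The 3 lists called by camera differ from these gene counts, since 80 of 100 splits gave at least 3 and the highest other gave 12, so as many called lists are common by chance. Library kit or batch differences stay open, because the labels assign neither to libraries.

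The second pattern is that radial glia and astrocyte markers moved in both directions. A lower share of radial glia stays open. It would raise markers of other lineages, but 49 neuronal and oligodendrocyte lineage markers had a median of -0.27 (exact permutation p = 0.18), which does not decide. It would also lower radial glia markers, of which 15 of 20 lay below 0, with a median of -0.47. At least 15 lay on one side in 220 of all splits of the libraries. Sox2 (360 against 377 TPM), Nes (382 against 342 TPM) and Sox9 (136 against 143 TPM) changed little and were not called, so the list's own values are mixed. The proneural list was not among the 49 markers of other lineages. Its 8 tested members all lay above 0 (exact permutation p of 0.268 for the median and 0.00866 for the mean, neither adjusted over lists). Camera placed that list higher (adjusted p = 0.000792), but not with an estimated correlation (adjusted p = 0.918). That 6 radial glia and astrocyte markers rose (Vim, Hes1, Cd44, Fgfr3, S100b and Sparcl1) was first taken as a test but is part of the pattern itself and decides nothing. Admixed fibroblasts as the source of the raised Anxa2 are argued against by the summed TPM of Col1a1, Col1a2, Col3a1, Dcn and Lum, which was at most 1.58 in any overexpression library, where Anxa2 had 42.5 TPM or more. A change of expression within the cells with Klf5 overexpression, or a shift between precursor states, may remain, and these were not tested apart.

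The third pattern is in replication-dependent histone genes: 59 of 65 lay below 0 and 2 fell. At least 59 lay on one side of 0 in 61 of all splits of the libraries. Their median was -0.42, with an exact permutation p of 0.0433, or 0.0727 adjusted over 8 groups, and camera with an estimated correlation gave an adjusted p of 0.189, so a lower level of the group is not established. Most of these transcripts lack a poly(A) tail, and a lower yield of such RNA stays open: 9 small RNAs without poly(A) tails had a median of -0.32, in the direction this explanation needs, although their own exact permutation p was 0.353. Fewer cells in S phase cannot be told apart from it, since the DNA replication list lay lower but did not pass (camera adjusted p = 0.102), and was called lower in 4 other fits: without a filter, with the replicate block, without control library 2 and without overexpression library 1.

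The effect of Klf5 overexpression was compared between XX and XY embryos, with sex read from Xist and Y-linked genes (3 XY and 3 XX controls, 2 XY and 3 XX with overexpression). In limma 0 genes off the sex chromosomes had an interaction past the adjusted threshold, and 465 of 13549 genes had an unadjusted p under 0.05. With no interaction a share of 0.05 of the tested genes would be there on average, and the count lies below that share. The prediction set beforehand took 0 such genes as evidence against a difference, which was too strict a reading: the median standard error of the interaction was 0.36 on the log2 scale, so differences of moderate size would be missed. Even the smallest limma interaction p, 0.000284 for Itpr2, had an adjusted p of 0.973, so larger differences could be missed as well.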
